A study of Mus musculus with 4 samples.

How the data were processed

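Gene expression was measured by RNA sequencing in long-term haematopoietic stem cells of C57BL/6 mice aged 8 to 12 weeks. Per the labels, the cells were sorted as lineage-negative, Sca-1-positive and Kit-positive (LSK) cells without CD34 and Flk2, lysed directly, and made into libraries of polyA RNA by SMARTer, a template-switching method for small inputs. There were 2 wild-type (WT) libraries and 2 libraries of Sin3B knockout (KO) cells. Nothing in the labels says whether the 2 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The titles number the libraries 1 and 2 in each group, while the descriptions number the same libraries 1 and 3; the numbers of the titles are used here.

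The submitters' processing notes name Bowtie, DESeq and the mouse build mm9, with no versions; the counting tool and annotation are not given in the sources used here. The authors deposited 1 table of 9796 genes. Its library columns hold a signal that the authors made by dividing the read count of a gene by 1 size factor per library, as the deposited values themselves show. Every value was a whole multiple of the library's step within 0.01 of a step, and the step was 1.14 for WT 1, 0.989 for WT 2, 0.961 for Sin3B KO 1 and 0.892 for Sin3B KO 2. Per the file headers, the table also gives the authors' own comparison, as a log2 fold change with its standard error, a test score (the fold change divided by its error), a p-value and an adjusted p-value. The authors' log2 fold changes were smaller than the ratios of the library values for weakly expressed genes, as shrunken estimates are.

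The table lists genes with a mean of at least 120.2 over the libraries, so weakly expressed genes were not analysed here. A further 552 genes (5.63%) have the authors' comparison and no library values, 310 of them with names that start with a digit and 225 with names in lower case; they were left out of all tests. Names of 15 genes had turned into dates, and hyphens in names had become full stops. With a step taken as 1 read, the depth was 9950979 reads in the listed genes for WT 1, 11754067 for WT 2, 12637960 for Sin3B KO 1 and 13700630 for Sin3B KO 2. The median gene had 607, 715, 737 and 788 reads in these libraries, in that order.

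Before the data were examined, a count model had been chosen for raw counts and limma for normalised values. As the table holds normalised values, the choice written for them was kept and no count model was run, although the steps give whole numbers for the listed genes. Accordingly limma 3.58.1 in R 4.3.3 was used on log2(value + 1) with a trended prior. Fold changes are on that scale. Genes with a value of at least 1 in 2 or more libraries were kept, which were all 9244 genes with values. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The prior supplied 6.62 degrees of freedom beside the 2 of the libraries, and the median half-width of a 95% confidence interval was 0.60 on the log2 scale, a 1.51-fold difference.

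Before the data were examined, 25 gene lists were written. The 22 lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Named genes were Sin3b and Sin3a, then up to 12 genes per direction past the threshold, filled to 5 per direction by the smallest unadjusted p where fewer passed, with groups that do not overlap and without predicted names; and from each list up to 4 members that passed, or else its 2 most abundant members. Some genes that the rule takes are not reported here. Other genes named below were chosen after their values were seen. The authors' own calls are given beside these.

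The test was checked on simulated data for the 9244 genes, with 200 genes changed in each of 20 rounds. It recovered 11.2% of the genes changed by 1 on the log2 scale and 70.3% of those changed by 2, with 4.35 false calls per round. A list of 30 genes shifted by 0.5 was called in 20 of 20 rounds and unshifted lists in 0, but the simulated genes varied independently of each other, which real genes do not.

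The alternatives were 3 other scalings, pseudocounts of 0.1 and 5, other thresholds, a test against a fold of 1.5, the replicate number as a block, and each library left out in turn. Trimmed mean scaling and a filter on a mean of at least 500 were chosen after seeing the data. An Ensembl gene identifier was given for 9019 of the tested genes. A GRCm38 annotation was used through these identifiers for exon lengths and for the order of genes, and no coordinates are given because the authors' build is another.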

Results

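The study compared gene expression between WT and Sin3B KO long-term haematopoietic stem cells, the rare marrow cells that sustain all blood lineages, to find genes regulated by Sin3B. Sin3B is a scaffold of histone deacetylase complexes that repress transcription. Each genotype had 2 libraries (n = 2 throughout), with between 9950979 and 13700630 reads in the listed genes. Values are normalised read counts, given as mean ± SD.

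Sin3b itself (ENSMUSG00000031622) was lower in both Sin3B KO libraries. Its level was 1673 ± 214 (SD, n = 2) in WT and 701.0 ± 77.0 (SD, n = 2) in Sin3B KO cells, a 2.38-fold lower value (log2 fold change -1.25, SE 0.22). The individual values were 1522 and 1825 in WT and 755.4 and 646.5 in the KO, so reads of the gene remained in the KO libraries. The difference did not pass the threshold over all genes (limma, Benjamini-Hochberg adjusted p = 0.548). In the authors' deposited table the log2 fold change of Sin3b was -1.03 with an adjusted p of 0.0025. The paralog Sin3a, the scaffold of the related complex, had 2439 ± 412 in WT and 2338 ± 56.8 in the KO (log2 fold change -0.05). The 20 measured Sin3 complex subunits had a median log2 fold change of -0.21, with 8 above 0 and 12 below, and did not pass as a list (limma camera, Benjamini-Hochberg adjusted p = 0.396). The most abundant were Ogt, an O-GlcNAc transferase (6895 ± 497 and 5899 ± 958), and Kdm5a, a histone demethylase (4477 ± 1404 and 5940 ± 317).

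Among single genes, the highest-ranked difference was in Crbn, the substrate receptor of a ubiquitin ligase, at 1060 ± 318 in WT and 3005 ± 383 in Sin3B KO cells (log2 fold change 1.53, SE 0.25). Nov, a secreted matrix protein, was at 474.4 ± 192 and 1477 ± 218 (log2 fold change 1.69, SE 0.31), and Commd10 at 390.9 ± 158 and 1225 ± 236 (log2 fold change 1.69, SE 0.32). Iigp1, an interferon-induced GTPase, had a log2 fold change of 1.14 and Tpp1, a lysosomal peptidase, of 0.93. Lower values in the KO were found for Alcam, a cell adhesion molecule (689.7 ± 34.0 and 242.0 ± 66.3, log2 fold change -1.53, SE 0.30), and P2ry2, a receptor for extracellular nucleotides (436.8 ± 61.1 and 131.9 ± 20.1, log2 fold change -1.72, SE 0.35). Bex1 had a log2 fold change of -1.31. None of these passed in the main fit: 0 of 9244 genes did (limma, smallest Benjamini-Hochberg adjusted p = 0.548). With the replicate number as a block 27 genes passed, Crbn, Nov, Commd10, Iigp1, Tpp1, Alcam, P2ry2 and Bex1 among them. What the number marks is not stated. At an unadjusted p under 0.05 there were 824 genes (8.91%), 459 higher and 365 lower in the KO. The 2 groups did not overlap for 4075 genes (44.1%), where chance gives 33.3% if the libraries are interchangeable. Same-numbered libraries share a pattern and genes are not independent, so the excess was not tested as an effect of genotype. In 1 left-out setting each, Ngp (without WT replicate 2) and Atp1b2 (without Sin3B KO replicate 2) passed.

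**Figure D1:**
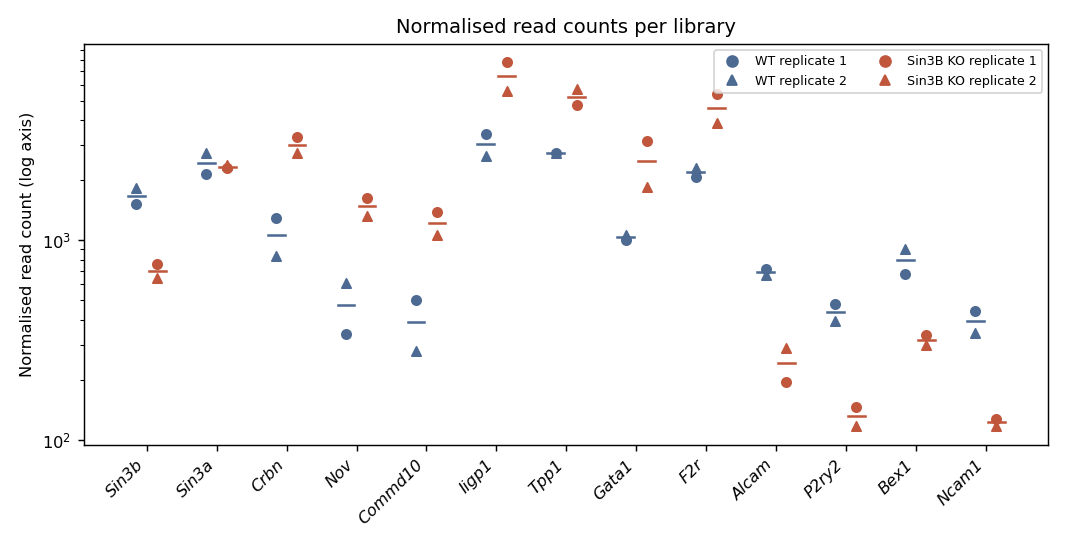
Normalised read counts of selected genes (log axis) in each library, with circles for replicate 1, triangles for replicate 2 and a line at each group's mean of 2 libraries. Sin3b lay at 1522 and 1825 in WT and at 755.4 and 646.5 in Sin3B KO.

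The authors' deposited table calls 31 genes at an adjusted p under 0.05, 20 higher and 11 lower in Sin3B KO cells, and 931 genes at an unadjusted p under 0.05. Besides the genes above, those higher in the authors' deposited table included F2r, the thrombin receptor (log2 fold change 0.91), Gata1, the erythroid and megakaryocytic transcription factor (0.99), Bank1, a B cell adaptor (1.20), and the DNA replication genes Rrm1 (0.68), Fen1 (0.75) and Rpa1 (0.74). Lower in the authors' deposited table were Meg3, an imprinted noncoding RNA (-1.28), the adhesion gene Ncam1 (-1.04), Arhgef28 (-1.05), Iqgap2 (-0.78) and Rn45s, the ribosomal RNA precursor (-0.73). Of the 30 called genes with library values, 30 had the same sign and non-overlapping groups here, and 30 were under an unadjusted p of 0.05, but 0 passed the limma threshold. Meg3 varied within WT, at 981.7 and 272.0, against 112.5 and 84.7 in the KO.

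Genes of the interferon response were higher in Sin3B KO cells. Of 28 measured members, 27 had a log2 fold change above 0, with a median of 0.44 (1.35-fold) and quartiles of 0.28 and 0.60. Ifit1 was at 933.9 ± 17.9 in WT and 1600 ± 20.6 in the KO, and Iigp1 at 3015 ± 534 and 6672 ± 1578. In 19 members both KO values lay above both WT values, and in 0 below. The list passed (limma camera, Benjamini-Hochberg adjusted p = 4.5e-07). With an estimated correlation its unadjusted p was 0.165 (limma camera, Benjamini-Hochberg adjusted p = 0.960), which ends the call. Over all genes 0 members passed, and adjusted over the list alone 3 did, Iigp1 and Ifit1 among them. The 11 measured members of the NF-kB and cytokine list had a median log2 fold change of -0.40, with 10 below 0. Nfkbia, the inhibitor of NF-kB, was at 3488 ± 371 and 2632 ± 32.6, and Nfkb1 at 2418 ± 352 and 2290 ± 133. This list passed narrowly (limma camera, Benjamini-Hochberg adjusted p = 0.0403). With an estimated correlation its unadjusted p was 0.218 (adjusted 0.960). Its call was lost without WT replicate 2 (median -0.12), without Sin3B KO replicate 1 (-0.13) and without Sin3B KO replicate 2 (-0.24), and among genes with a mean of at least 500 (-0.14).

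Cell cycle genes were higher in Sin3B KO cells as lists. The G1/S and DNA replication list had 27 of 34 measured members above 0 and a median log2 fold change of 0.40. Rrm1, the large subunit of ribonucleotide reductase, was at 3115 ± 142 in WT and 5321 ± 385 in the KO, Fen1, a flap endonuclease, at 3515 ± 448 and 6459 ± 1403, and the replicative helicase subunit Mcm3 at 4834 ± 60.3 and 6930 ± 581. Mcm6, the most abundant member, was at 7376 ± 260 and 7504 ± 2183. The list passed (limma camera, Benjamini-Hochberg adjusted p = 2.9e-04), with an unadjusted p of 0.320 (adjusted 0.960) with an estimated correlation. The G2/M and mitosis list had 24 of 29 members above 0 and a median of 0.50 (adjusted p = 4.2e-04 by limma camera with Benjamini-Hochberg adjustment). With an estimated correlation its unadjusted p was 0.432 (adjusted 0.960). Top2a was at 2412 ± 569 and 2930 ± 352, while Mki67, the proliferation marker, was at 1765 ± 699 and 1760 ± 799. In neither list did a member pass, over all genes or adjusted over the list alone. Without Sin3B KO replicate 1 both calls were lost (medians 0.21 and 0.18), and the G2/M call also without WT replicate 2 (0.19). G2/M genes also differed between the libraries numbered 1 and 2, with a median of 0.55 higher in replicate 1, and G1/S genes by 0.09. The 17 measured CDK inhibitors, pocket proteins and D cyclins had a median of 0.01 (limma camera, Benjamini-Hochberg adjusted p = 0.973), with Ccnd2 at 11812 ± 1665 and 12667 ± 2022 and Cdk4 at 5940 ± 905 and 7030 ± 86.5.

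**Figure D2:**
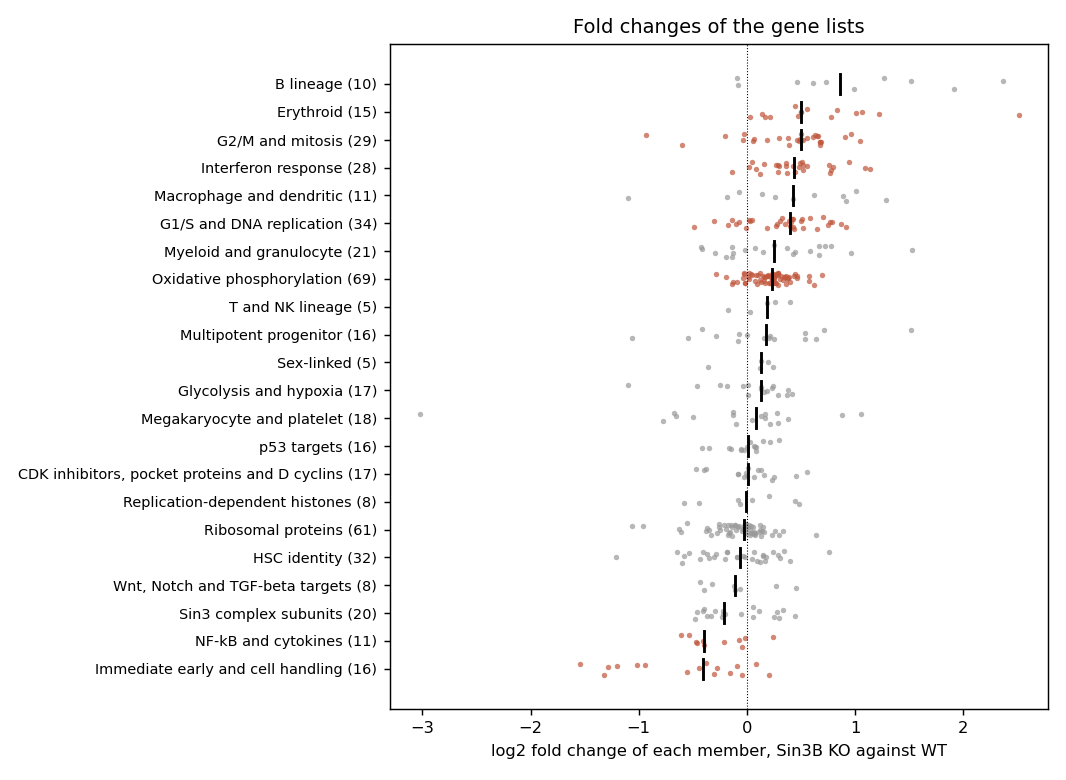
Log2 fold change (Sin3B KO against WT) of each measured member of the 22 tested lists, with the number of members in brackets and a bar at the median; lists that passed by camera with the preset correlation are coloured. The interferon list has 27 of 28 members above 0, and 0 lists passed with an estimated correlation.

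Stem cell genes went both ways. The HSC identity list had 14 of 32 members above 0 and a median log2 fold change of -0.06 (limma camera, Benjamini-Hochberg adjusted p = 0.204). Txnip was at 19212 ± 2818 in WT and 14895 ± 1783 in the KO. The list passed without WT replicate 1 (median -0.09), without Sin3B KO replicate 2 (-0.23) and among genes with a mean of at least 500 (-0.09). Of the sort gate, Kit was at 20057 ± 3213 and 20356 ± 723 and Cd34 at 5727 ± 1105 and 5378 ± 346, and the median of its 4 measured genes was -0.02. The 16 multipotent progenitor genes had a median of 0.18 and did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.973), with Myc at 8525 ± 568 and 10161 ± 1214. They passed as higher without WT replicate 1 (median 0.51) and without Sin3B KO replicate 2 (0.35), and as lower without WT replicate 2 (-0.38).

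Erythroid genes were higher in the KO as a list on the log2 scale, with 15 of 15 measured members above 0 and a median log2 fold change of 0.50 (limma camera, Benjamini-Hochberg adjusted p = 0.0087). For some members the mean count was nevertheless lower in the KO: Alas2 (381.9 and 296.0), Slc4a1 (596.9 and 399.8) and Epb4.2 (183.1 and 171.5). Their values in WT 2 were low, at 7.91, 0 and 73.2. Members above 0 numbered 8 without WT replicate 2 and 8 without Sin3B KO replicate 1. They numbered 14 without WT replicate 1 and 15 without Sin3B KO replicate 2. The unadjusted camera p was 0.381 (adjusted 0.960) with an estimated correlation. Gata1 was at 1034 ± 41.6 in WT and 2493 ± 920 in the KO and was the only member to pass when adjusted over the list alone, while the abundant Car2, a carbonic anhydrase, was at 50069 ± 1497 and 56276 ± 2765 and Nfe2 at 7948 ± 1464 and 8038 ± 240. The call was lost without WT replicate 2 (median 0.12) and without Sin3B KO replicate 1 (0.04), where camera's direction turned. The median was 1.13 without WT replicate 1 and 1.47 without Sin3B KO replicate 2. Erythroid genes were also higher in replicate 1 than in replicate 2 libraries, by a median of 1.23.

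Genes of some blood cell lineages differed between the numbered libraries of both genotypes. Myeloid and granulocyte genes were higher in the libraries numbered 1 by a median of 2.34 and B lineage genes by 2.62 on the log2 scale, while their medians between genotypes were 0.25 (21 genes) and 0.86 (10 genes). Mpo, a neutrophil enzyme, was at 17017 and 2359 in WT 1 and WT 2 and at 19732 and 5569 in Sin3B KO 1 and 2, and Lyz2 at 8784 ± 5811 and 7224 ± 2164. Neither list passed with the 4 libraries (limma camera, Benjamini-Hochberg adjusted p = 0.973 and 0.201). Myeloid genes passed as higher without WT replicate 1 (median 2.13) and without Sin3B KO replicate 2 (0.71) and as lower without WT replicate 2 (-1.22), and their median was -0.35 without Sin3B KO replicate 1. B lineage genes passed without WT replicate 1 (median 2.95) and without Sin3B KO replicate 2 (2.60), while the median was -0.51 without WT replicate 2 and -0.12 without Sin3B KO replicate 1. Cd79b was at 1431 ± 221 and 1352 ± 221 and Cd72 at 783.3 ± 11.2 and 735.0 ± 37.6, while Bank1, at 104.4 ± 63.7 and 496.1 ± 113, passed when adjusted over the B lineage list alone. The 18 megakaryocyte and platelet genes had a median of 0.09 and a mean of -0.13 (limma camera, Benjamini-Hochberg adjusted p = 0.973), with Mmrn1 at 7525 ± 238 and 8781 ± 1691. Of these, F2r, at 2185 ± 157 and 4611 ± 1078, passed when adjusted over the list alone. Between the numbered libraries the megakaryocyte list differed by a median of 0.07, yet it passed as higher in replicate 1 (limma camera, Benjamini-Hochberg adjusted p = 0.0111). Its mean level was 0.45 in WT 1 and -0.32 in WT 2, and 0.02 and -0.15 in Sin3B KO 1 and 2. Macrophage and dendritic genes were higher in replicate 1 by a median of 0.42 (limma camera, Benjamini-Hochberg adjusted p = 0.0226). For T and NK genes the median difference was -0.04. T and NK genes had a median of 0.18 between genotypes (5 genes, limma camera, Benjamini-Hochberg adjusted p = 0.636) and included Gata3 (1644 ± 418 and 1675 ± 440) and Nkg7 (1396 ± 291 and 1908 ± 817). Macrophage and dendritic genes had a median of 0.43 (11 genes, limma camera, Benjamini-Hochberg adjusted p = 0.204), with the antigen presentation genes Cd74 at 5048 ± 1183 and 5979 ± 386 and H2.Aa at 1591 ± 294 and 1499 ± 35.5. That list passed without WT replicate 1 (median 0.63) and without Sin3B KO replicate 2 (0.61), and its median was 0.12 without WT replicate 2 and 0.21 without Sin3B KO replicate 1. Of the endothelial and stromal list 4 genes were measured (median 0.62, not tested), with Cxcl12 at 284.8 ± 334 and 756.2 ± 956 and Pdgfrb at 524.8 ± 20.5 and 389.0 ± 208.

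**Figure D3:**
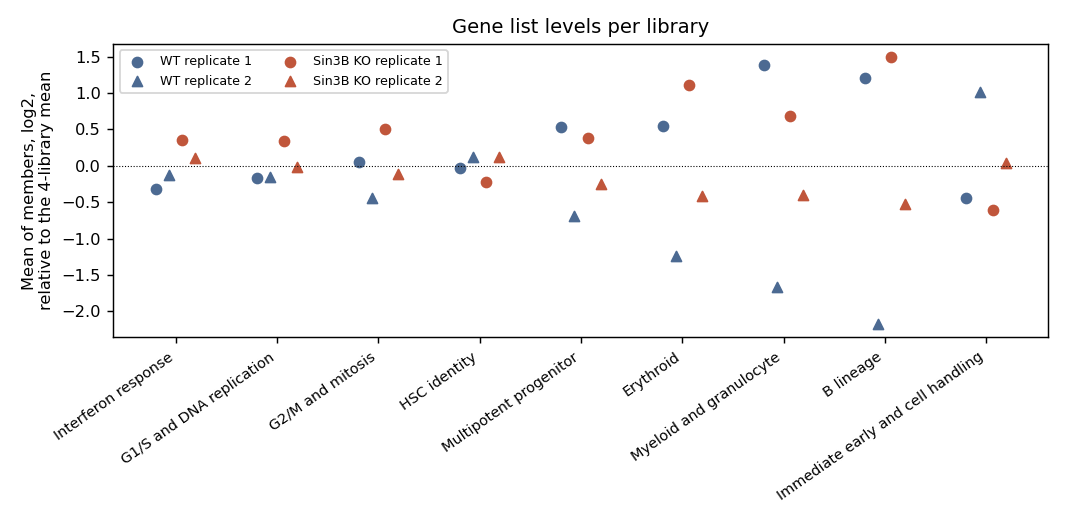
Mean log2 level of the members of 9 lists in each library, relative to the mean of the 4 libraries, with circles for replicate 1 and triangles for replicate 2. B lineage, myeloid and erythroid genes lie higher in the replicate 1 libraries of both genotypes, and immediate early genes lower.

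Immediate early genes, which are induced within minutes of stimulation or cell handling, had a median log2 fold change of -0.41, with 14 of 16 members below 0 (limma camera, Benjamini-Hochberg adjusted p = 0.0132). The unadjusted camera p was 0.335 (adjusted 0.960) with an estimated correlation. Without WT replicate 2 the median was 0.24, the direction turned, and without Sin3B KO replicate 1 the call was lost (median -0.28). Fos was at 541.6 in WT 1 and 5576 in WT 2, and at 409.4 and 2008 in Sin3B KO 1 and 2, and the list was lower in replicate 1 libraries by a median log2 difference of -0.89. Junb was at 339.0 ± 52.7 and 139.5 ± 27.0, Zfp36 at 4933 ± 3145 and 4467 ± 2375, and Dnajb1 at 4194 ± 1325 and 4725 ± 44.0.

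Genes of oxidative phosphorylation were slightly higher in Sin3B KO cells, with 59 of 69 members above 0 and a median log2 fold change of 0.23 (limma camera, Benjamini-Hochberg adjusted p = 2.9e-04). The unadjusted camera p was 0.383 (adjusted 0.960) with an estimated correlation. The ATP synthase subunits Atp5a1 and Atp5b were at 12839 ± 2798 and 8797 ± 904 in WT and at 16662 ± 412 and 9857 ± 2094 in the KO. The call was lost without WT replicate 1 (median 0.12) and without Sin3B KO replicate 1 (0.20). Across genes, fold changes were lower for genes with longer exons (Spearman rho -0.235 over genes, which are not independent replicates), and the median of this list was 0.14 after removing that trend. The ribosomal RNA precursor Rn45s made up 1.23% and 0.858% of the listed signal in WT 1 and WT 2 and 0.627% and 0.453% in Sin3B KO 1 and 2. The 10 most abundant genes made up 4.32% and 4.25% against 3.49% and 3.61%, but Rn45s is among them, so this is not a separate sign. A difference between the genotypes' libraries in preparation stays open for small shifts such as that of the oxidative phosphorylation list. The glycolysis and hypoxia list had a median of 0.13 (17 genes, limma camera, Benjamini-Hochberg adjusted p = 0.973), with Aldoa at 10434 ± 2171 and 11788 ± 837 and Pkm at 7847 ± 1800 and 8700 ± 1368. Adjusted over this list alone, the aldolase gene Aldoc passed, at 676.5 ± 60.2 and 314.4 ± 10.8. In the lists whose counts are not given, 0 members passed in either way. The 61 ribosomal protein genes had a median of -0.03 (limma camera, Benjamini-Hochberg adjusted p = 0.273), with Rpl4 at 14746 ± 2486 and 17514 ± 1.34, and passed as lower without WT replicate 1 (median -0.14).

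The remaining lists did not pass with the 4 libraries. The 16 p53 targets had a median log2 fold change of 0.01 (limma camera, Benjamini-Hochberg adjusted p = 0.973), with Sesn1 at 3081 ± 295 and 3261 ± 288 and Ccng1 at 1506 ± 165 and 1606 ± 364. The 8 targets of Wnt, Notch and TGF-beta signalling had a median of -0.11 (limma camera, Benjamini-Hochberg adjusted p = 0.636), with Znrf3 at 1360 ± 113 and 1308 ± 195 and Tgfbr2 at 809.5 ± 37.0 and 618.8 ± 83.1. The 8 replication-dependent histone genes, whose mature RNAs mostly lack a polyA tail, had a median of -0.01 (limma camera, Benjamini-Hochberg adjusted p = 0.973), with Hist1h1c at 484.6 ± 137 and 649.2 ± 60.5 and Hist1h2bc at 403.9 ± 28.5 and 419.6 ± 71.3. For the CDK inhibitor, megakaryocyte, p53 and histone lists, the median, the mean or the test differed in sign. Of the mitochondrially encoded list 0 genes were among those with values. Sex-linked genes had a median of 0.13 (5 genes, limma camera, Benjamini-Hochberg adjusted p = 0.973), and Xist and Ddx3y were both read in each of the 4 libraries, Xist at 2771 ± 2192 and 1793 ± 113 and Ddx3y at 1377 ± 481 and 1451 ± 48.7. The sex-linked list passed without WT replicate 1 (median 0.48), and its median was -0.24 without WT replicate 2.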

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

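4933404O12Rik stands out as a call in the authors' deposited table, higher in Sin3B KO cells with a log2 fold change of 0.8474 (authors' adjusted p 0.0383), that belongs to the genes without library values, so its values per library were not analysed here.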

How the results depend on the processing

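The filter on a mean of at least 500 and the trimmed mean scaling were chosen after seeing the data. The number of genes that passed was 0 under every scaling, pseudocount, filter and threshold tried (limma), and between 0 and 1 with a library left out. With the replicate number as a block, 27 genes passed (15 higher, 12 lower, 20 of them also called in the authors' deposited table), and Sin3b passed with a log2 fold change of -1.25 (limma, Benjamini-Hochberg adjusted p = 0.0282). That adjusted p ranged from 0.0282 to 0.552 over the settings other than the test against a fold of 1.5. The deviations of same-numbered libraries from their group means had a correlation of 0.465 across genes, so these libraries share a pattern. With 2 pairs and no label that says what the number marks, the source of this pattern is not known. Sin3b was lower in each setting, with a log2 fold change between -1.38 and -1.12 with a library left out.

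The number of lists that passed was 7 under the scalings, pseudocounts and the filter tried, 9 with the block (B lineage and macrophage genes besides those 7), 0 with an estimated correlation and 0 by fry. Under the filter on the mean, the HSC identity list took the place of the NF-kB list. With a library left out, the number ranged from 1 (without Sin3B KO replicate 1) to 13 (without WT replicate 1). With a library left out, the median log2 fold change ranged from -0.38 to 0.51 for multipotent progenitor genes, from -1.22 to 2.13 for myeloid genes, from -0.93 to 0.24 for immediate early genes and from 0.0403 to 1.47 for erythroid genes. In each of these 4 lists the direction of the test turned in 1 or more of the fits. The cause was not tested beyond the differences between numbered libraries given above. The interferon list passed in 11 of 13 settings, those without each library included. With a library left out, the lone library of its group is assumed to vary like the other group. Of 600 values of named genes under the alternatives, 592 did not pass and 8 newly passed. Those 8 were Crbn, Nov, Commd10, Iigp1, Tpp1, Alcam, P2ry2 and Bex1 with the block. As no gene passed in the main fit, the 592 are no sign of stability. The sign changed in 58 values of 29 genes, 46 with a library left out and 12 under another scaling; none of these 58 passed. Upper quartile scaling shifted the median of all genes from 0.03 to -0.08, and the list medians with it. No gene was removed by the filters written beforehand, so they tested nothing, and the planned count tests were not run, as limma was the test chosen beforehand for normalised values. The spread between libraries leaves a median 95% interval of 1.51-fold either way for a gene.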

Other observations

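Of 22 measured adhesion and matrix genes, chosen after the data were seen and not tested as a set, 10 had a log2 fold change above 0 and 12 below, with a median of -0.01. Alcam, Ncam1 and Mmp2 were lower in both Sin3B KO libraries, with Mmp2, a matrix metalloprotease, at 243.6 ± 63.4 (SD, n = 2) in WT and 60.8 ± 6.49 in the KO. Itgb2, the shared chain of leukocyte integrins, was higher, at 1362 ± 625 and 2666 ± 137, and Itgb3, the platelet integrin chain, lower, at 1430 ± 505 and 832.7 ± 278, with a log2 difference of -1.49 within replicate 1 and only -0.06 within replicate 2. None of the 22 passed by limma without a block, and 6 were under an unadjusted p of 0.05. Among 8 imprinted genes, also chosen after the data were seen and not a full set of such genes, Meg3 had a log2 fold change of -2.39. The others of these 8 lay between -0.39 (Igf2r) and 0.25 (Sgce). Ppbp, a platelet chemokine, was at 3854 in WT 1 and at 89.0, 121.1 and 41.9 in WT 2, Sin3B KO 1 and Sin3B KO 2.

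The tests of other cells in the sorts were chosen after the lists had been seen, and the interferon test was split by cell type after a first run on myeloid, B lineage and erythroid cells together had decided nothing; those of scaling, exon length, other splits and neighbouring genes were written before. The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split called 7 lists and 0 genes, and the highest other called 11 lists; all 3 splits called at least 7 lists. That highest split, by replicate number, called 85 genes, which points to a structure of the libraries, and the split across genotype and number called 10 lists and 0 genes. Higher there in WT 2 and Sin3B KO 1 were the G1/S (median 0.21), oxidative phosphorylation (0.18) and immediate early lists (0.35), with limma camera Benjamini-Hochberg adjusted p of 3.4e-04, 1.6e-04 and 3.4e-04, so the passing of these lists between genotypes is matched by a split that is not by genotype. In the split by number, replicate 2 against replicate 1, the G2/M (median -0.55), erythroid (-1.23) and immediate early lists (0.89) passed too. Their limma camera Benjamini-Hochberg adjusted p were 1.1e-09, 1.7e-14 and 2.0e-11, so these lists are matched by that split as well. With the number as a block, the real comparison called 9 lists.

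The rise of the interferon list was weighed against other cells, scaling and length. Libraries numbered 1 and 2 differ in myeloid and B lineage genes by medians of 2.34 and 2.62. The list's median difference between them was 0.03751 (95% bootstrap interval over genes, not libraries, -0.10 to 0.15), where the genotype median was 0.44. The WT and KO pairs went opposite ways. The list's mean level was -0.32 in WT 1 and -0.13 in WT 2, but 0.35 in Sin3B KO 1 and 0.10 in Sin3B KO 2. The test required B lineage genes to differ more between numbers than between genotypes, which held only narrowly (lower bound 0.89 against 0.86). The values lean against such cells as the whole cause but do not exclude them. Over the other scalings the lowest list median was 0.3234. A scaling moves all genes alike, and these moved the median of all genes only from 0.03 to as low as -0.08. This outcome was therefore nearly fixed in advance and decides nothing, beyond the list staying above the median of all genes. The values argue against exon length, with a list median of 0.4409 after removing that trend. Erythroid cells stay open, as the lower bound of their genes' difference between numbers, 0.4567, lies under the 0.50 between genotypes, and so do T and NK, megakaryocyte and macrophage cells, whose highest genotype median was 0.4266 (macrophage genes), although the sort removes lineage-positive cells. A response in the Sin3B KO cells and variation between animals or sorts stay open too, as the list also passed in the split across genotype and number (median 0.20, limma camera, Benjamini-Hochberg adjusted p = 7.6e-04).

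The rise of the cell cycle lists could come from more cycling progenitors in the KO sorts. The G1/S median difference between numbered libraries was 0.09214 (95% bootstrap interval 0.05 to 0.26), which does not settle it against a genotype median of 0.40. For G2/M that difference was 0.5461, as such progenitors would give, but the progenitor list was higher by only 0.18 in the KO (interval -0.08 to 0.54), where 0.89 would be needed; this progenitor part was applied after the other had been seen, and without it the test alone would favour progenitors. Exon length argues against itself as the whole cause, with medians of 0.3622 (G1/S) and 0.5452 (G2/M) after its removal. Progenitors and a change within stem cells cannot be told apart here.

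The rise of the erythroid list might come from late erythroid cells. The mean level of their 6 measured genes, such as Slc4a1 and Alas2, was higher in the KO by 0.9275 (95% t interval between libraries -12.5 to 14.3). For the 11 other members of the list it was higher by 0.56. With so wide an interval from 2 libraries per genotype, the test could not have decided either way, so this stays open. The test was also rewritten after earlier forms had been run, 1 of which argued against late cells on number 1 alone. Between libraries of the same number the median difference of the late genes was -0.40 for number 1 and 1.72 for number 2. For the 11 other members it was 0.87 and 0.25. Each of these values comes from 1 library per genotype. Earlier erythroid cells were not tested. Slc4a1 was at 1194, 0, 748.7 and 50.8 in WT 1, WT 2, Sin3B KO 1 and Sin3B KO 2, though the sort removes lineage-positive cells.

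DNA flanking the targeted allele could also differ between genotypes. Of the 50 measured genes nearest to Sin3b on its chromosome, 2 were under an unadjusted p of 0.05, a share of 4% (exact 95% interval 0.49% to 13.7%) against 8.91% of all genes. The interval is too wide to exclude a raised share.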
